A study of Triticum aestivum with 12 samples.

How the data were processed

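Root RNA of wheat (Triticum aestivum) was measured by stranded poly(A) RNA sequencing in 12 libraries, 3 in each of 4 groups: cultivar KN9204 or BN207 under normal or low potassium for 14 days. Group and replicate number were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol, enriched for polyadenylated molecules with oligo-dT beads, fragmented and made into libraries with a TruSeq stranded kit. HISAT2, StringTie and edgeR are named in the submitters' processing notes without versions. The genome build, the counting command and its strand setting are not given in the sources used here.

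The deposited table held 87634 rows, each with an estimated count and an FPKM value (fragments scaled to transcript length and library size) per library, beside gene names, descriptions and GO and KEGG terms written by the authors. The authors' estimated counts were whole numbers in all 87634 rows and were used as deposited. They were not counts of single fragments: 41.9% of values from 1 to 40 were multiples of 4, against 25% for evenly spread values, and each of the 9 multiples of 4 up to 36 was more frequent than both neighbouring values. A fragment was taken to weigh about 4 counts, an assumption, since the counting step is not given. Totals ranged from 75924470 to 88552154 counts per library. The detection floor was set at 3 fragments, or 12 counts, per library, and a fold against a group at 0 in every library was computed against that floor and is a lower bound. If a fragment weighed less than 4, the floor would be lower and these bounds would still hold. If it weighed more, they would be too high. Floors cover counting error only. The authors' FPKM values, as deposited, were used for filtering and for the levels printed, and not for the tests.

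The test had been planned on the log2 scale of FPKM before the data were examined, with a count model if counts were present. Because counts were present, edgeR's quasi-likelihood test (edgeR 4.0.16 with limma 3.58.1 in R 4.3.3) was used. Rows with FPKM of at least 0.5 in at least 3 libraries were kept, which left 62053. Of these, 32478 were listed under loci assembled by the authors, 3734 had no gene name and 197 joined several gene names. Libraries were scaled by TMM, dispersions were estimated robustly over all 12 libraries with a term for each group, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. Positive log2 values mean higher in low potassium, or higher in KN9204 for the cultivar comparisons. The interaction is the response in KN9204 minus the response in BN207. SE is an approximate standard error, the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. It is unreliable for genes near 0 in a group.

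A set of 27 gene lists was fixed by words in gene descriptions before the data were examined. Descriptions were present for 91.5% of tested genes, but only 36.7% (22791) had one that named more than a predicted, hypothetical or unknown protein, so most genes could enter no list. Each list was compared with all other genes by camera with a preset inter-gene correlation of 0.01 and adjusted over the 27 lists. The same test with the correlation estimated from the data is given beside each call lost with it. A further 2446 GO and KEGG terms with 10 to 500 tested members were tested in the same way. Counts of genes adjusted over the list alone are also given, and list medians were recomputed with genes at 0 in a whole group set to their bound.

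Genes named in the text were chosen by a rule fixed beforehand. For each potassium comparison it took the 8 largest rises and the 8 largest falls among called, described genes whose 3 low and 3 normal values did not overlap and whose higher mean was FPKM 1 or more. It took 5 per direction for the interaction and the cultivar comparisons, up to 3 called members per list, and the 3 potassium transporters with the highest mean FPKM. Part of these are named here, and a gene named outside the rule is said to have been chosen after its values were seen. Gene IDs, descriptions and terms are those of the deposited table, and a chromosome is given only as it appears in the gene ID. A reference gene table was compared with 58246 IDs and matched 0, so no coordinates are given.

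Wheat carries near-identical copies of most genes on its A, B and D genomes. How reads shared by such copies were divided is not given in the sources used here, so the value of a single copy is uncertain. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Pairs of replicates differed by more than counting noise, with a chi-square per gene of 3.89 to 7.48 over approximate fragments, and each was kept as a sample.

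The alternatives covered the filter, the scaling, the pseudocount, the test (limma on log2(FPKM + 1), and DESeq2 1.42.0), counts divided by 4, library weights, the replicate number as a block, the libraries in the fit and leaving out each replicate. The pipeline was tested on data simulated over 62053 genes. Far fewer genes were changed there than were called in the real comparisons, and genes were drawn independently. The rates below therefore describe the simulated data and may not hold for the real comparisons. For KN9204 low versus normal potassium it recovered 60% of 100 genes changed 2-fold and 85% of 100 changed 4-fold, and 5.3% of its calls were false. For BN207 it recovered 66% and 85%, with 7.2% false, and for the interaction 42% and 76%, with 7.7% false. For the cultivars it recovered 57% and 91% under normal potassium, with 6.8% false, and 63% and 91% under low potassium, with 5% false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.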

Results

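Root transcripts of wheat, a cereal whose genome holds A, B and D copies of most genes, were profiled in 12 libraries. Cultivar KN9204 (Kenong 9204) is labelled tolerant of potassium deficiency and BN207 (Bainong 207) sensitive to it, and each was sampled in 3 libraries under normal and 3 under low potassium after 14 days. Total estimated counts ranged from 75924470 to 88552154 per library, where a fragment was taken to weigh about 4 counts. Between 47591 and 49716 genes per library reached FPKM 1. Replicates of a group correlated at Pearson r of 0.973 to 0.986 of log2(FPKM + 1) across genes, which are not independent replicates. The first principal component (54.6% of variance) placed the KN9204 normal libraries at -204 to -201, the KN9204 low libraries at -105 to -101, the BN207 normal libraries at 61.2 to 69.4 and the BN207 low libraries at 227 to 255.

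**Figure D1:**
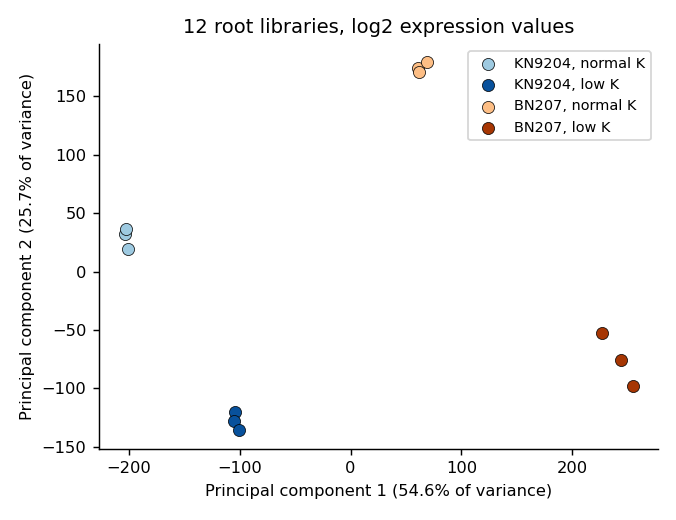
Principal component 1 (x axis, 54.6% of variance) against principal component 2 (y axis, 25.7% of variance) of the 12 libraries, one point per library, colored by group. The 3 libraries of each group lie together, and the KN9204 libraries lie at -101 or lower on the x axis while the BN207 libraries lie at 61.2 or higher.

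The first comparison asked which root genes of the tolerant cultivar KN9204 respond to low potassium. The 3 copies of potassium transporter 1, a carrier of the HAK family, rose from 7.7 ± 0.83 to 74.8 ± 1.7 FPKM (SD, n = 3; TraesCS4A02G410200, log2 fold change 3.17 ± 0.1 SE, edgeR adjusted p = 3e-11), from 16.7 ± 1.3 to 63.2 ± 3.3 (TraesCS4B02G310300, log2 1.81 ± 0.09) and from 13.5 ± 0.64 to 58.8 ± 2.7 (TraesCS4D02G308200, log2 2.02 ± 0.09). The 3 AKT1-like channel genes, chosen after their values were seen, also rose, from 7.16–9.05 to 24.4–28.9 FPKM (TraesCS3A02G233800, TraesCS3B02G265500 and TraesCS3D02G219600, log2 1.74, 1.32 and 1.8). AKT1 is the inward channel through which roots take up potassium. Peroxidase, lignin and histone lists had more falls than rises in the same roots.

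Of 52 tested potassium transporters and channels, 30 rose, 8 fell and 14 were not called in KN9204 (31 rose and 10 fell adjusted over the list alone). The list stood above all other genes, with a median log2 fold change of 0.85 (camera adjusted p = 6e-15, and adjusted p = 0.0018 with an estimated correlation). A putative Na+/K+ transporter gene, TraesCS7A02G418500, rose from 0.246 ± 0.057 to 3.58 ± 0.27 FPKM. Putative potassium transporter 16, TraesCS6D02G275100, fell from 2.56 ± 0.28 to 0.0365 ± 0.042 (log2 -6.16 ± 0.85, adjusted p = 0.00022). Among 74 CBL calcium sensors and CIPK kinases, the pair of families that switches AKT1 on, 36 rose and 13 fell (36 and 16 adjusted over the list alone; camera adjusted p = 2.2e-05, adjusted p = 0.12 with an estimated correlation). CBL-interacting protein kinase 14 rose in both named copies, from 0.604 ± 0.1 to 5.7 ± 0.72 FPKM (TraesCS4B02G120400) and from 0.815 ± 0.15 to 9.15 ± 0.25 (TraesCS4D02G118500). Calcineurin B-like protein 4, TraesCS1B02G370600, was at 0 in all 3 normal libraries and at 6.04 ± 1.2 FPKM in low potassium, at least 18.8-fold higher. Of 28 sodium and proton exchangers, HKT carriers and proton pumps, 13 rose and 6 fell (15 and 6 adjusted over the list alone; camera adjusted p = 0.00018, adjusted p = 0.071 with an estimated correlation). HKT1;4-2 (TraesCS2B02G451400), of the HKT family of sodium carriers, rose from 0.222 ± 0.1 to 7.25 ± 1.2 FPKM and HKT7-A1 (TraesCS2D02G428200) from 0.0315 ± 0.039 to 2.65 ± 0.034. HKT8 (TraesCS4B02G370800) went from 5.1 ± 1.1 FPKM to 0 in all 3 low libraries, at least 71.7-fold lower. The remaining calcium signalling list of 80 genes had 7 rises and 49 falls (9 and 51 adjusted over the list alone; camera adjusted p = 0.00018, adjusted p = 0.2 with an estimated correlation).

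**Figure D2:**
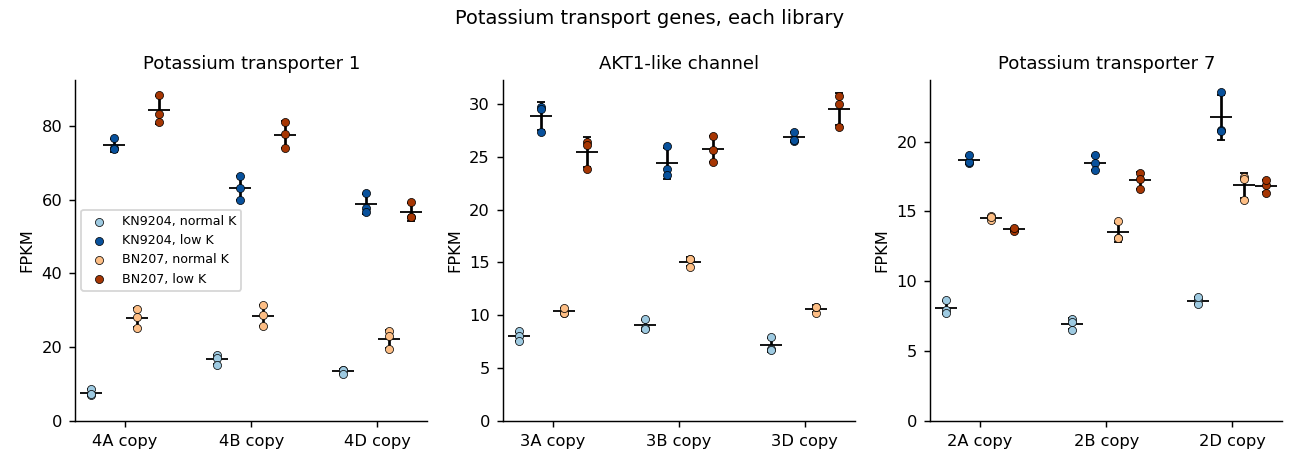
FPKM (y axes, from 0) of the A, B and D copies (x axes) of potassium transporter 1, the AKT1-like channel and potassium transporter 7, one point per library, with the mean and SD of each group of 3 in black. All 9 copies are higher in low than in normal potassium in KN9204, where the 4A copy of potassium transporter 1 goes from 7.7 to 74.8, and the 2A copy of potassium transporter 7 stays at 14.6 and 13.7 in BN207.

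Genes of other nutrients moved in both directions in KN9204. Among 82 genes of nitrate and ammonium transport and assimilation, 26 rose and 38 fell (30 and 38 adjusted over the list alone; camera adjusted p = 0.84), with a median log2 of -0.32, or -0.22 with bounds, against 0.23 and adjusted p = 0.0015 under a stricter filter. The high-affinity nitrate transporter genes were among those that fell: TraesCS6B02G044000 went from 0.915 ± 0.42 to 0.0053 ± 0.0092 FPKM and TraesCS6B02G044100 from 0.528 ± 0.11 to 0, at least 6.06-fold lower. Of 81 phosphate and sulfate transporter genes 21 rose and 27 fell (21 and 28 adjusted over the list alone; camera adjusted p = 0.6). A phosphate transporter, TraesCS5B02G470100, fell from 26.7 ± 2.8 to 7.53 ± 0.81 FPKM. Of 94 genes of iron and metal acquisition 35 rose and 17 fell (36 and 17 adjusted over the list alone; camera adjusted p = 0.11). In sugar transport and sucrose cleavage 35 of 93 genes rose and 24 fell (37 and 25 adjusted over the list alone; camera adjusted p = 0.016, adjusted p = 0.12 with an estimated correlation, and 0.23 by limma on log2(FPKM + 1)). Sucrose transport protein SUC3, TraesCS2B02G533300, rose from 0.0505 ± 0.02 to 1.12 ± 0.06 FPKM. Of 45 aquaporin genes, which encode water channels, 24 rose and 6 fell (24 and 6 adjusted over the list alone; camera adjusted p = 0.019, adjusted p = 0.56 with an estimated correlation, and 0.09 without KN9204 low potassium replicate 1). Aquaporin TIP2-3, TraesCS2A02G414100, fell from 39.5 ± 4 to 12.2 ± 0.99 FPKM.

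The list of class III peroxidases, secreted enzymes that act on the wall and on hydrogen peroxide, had 27 rises, 213 falls and 93 genes not called among 333 in KN9204 (28 and 223 adjusted over the list alone) and a median log2 of -1.14 (camera adjusted p = 1.5e-18, adjusted p = 0.071 with an estimated correlation). Its words also took in 17 ascorbate and glutathione peroxidases (1 rose, 2 fell), and the other 316 genes had 26 rises, 211 falls and a median of -1.25. Peroxidase 1, TraesCS1A02G318600, fell from 7.6 ± 0.78 to 0.0811 ± 0.071 FPKM, and a class III peroxidase, TraesCS1B02G330700, from 2.93 ± 0.65 to 0, at least 20.1-fold lower. In phenylpropanoid and lignin synthesis 14 of 92 genes rose and 59 fell (14 and 63 adjusted over the list alone; camera adjusted p = 2e-11, adjusted p = 0.082 with an estimated correlation). Laccase-22, TraesCS4D02G133800, went from 15.4 ± 3.1 to 1.27 ± 0.29 FPKM. Of 192 genes of wall loosening and remodelling 31 rose and 76 fell (32 and 79 adjusted over the list alone; camera adjusted p = 0.0024, adjusted p = 0.41 with an estimated correlation). Members described as inhibitors made up 11 of these (3 rose, 4 fell). Alpha expansin 6, TraesCS5B02G528500, fell from 0.913 ± 0.28 to 0.0154 ± 0.027 FPKM. Among 20 casparian strip and suberin genes, markers of the endodermis, 0 rose and 9 fell (0 and 9 adjusted over the list alone; camera adjusted p = 0.0024, adjusted p = 0.071 with an estimated correlation). A glycerol-3-phosphate acyltransferase of that list, TraesCS3B02G400000, fell from 11.8 ± 1.5 to 4.27 ± 0.73 FPKM. Pathogenesis-related, chitinase and thaumatin genes had 33 rises, 89 falls and 116 not called among 238 (33 and 89 adjusted over the list alone; camera adjusted p = 0.00032, adjusted p = 0.12 with an estimated correlation).

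Of 326 histone and replication genes, which mark dividing cells, 13 rose, 213 fell and 100 were not called in KN9204 (14 and 221 adjusted over the list alone), with a median log2 of -0.77 (camera adjusted p = 6.2e-11, adjusted p = 0.41 with an estimated correlation). Cyclin-D2-1-like, TraesCS5B02G199100, fell from 3.16 ± 1.1 to 0.717 ± 0.19 FPKM. That list also held 34 cyclin-dependent kinases, of which 5 rose and 6 fell. Ribosomal protein genes had 20 rises, 231 falls and 225 not called among 476 (20 and 239 adjusted over the list alone; median log2 -0.29, camera adjusted p = 0.00024, adjusted p = 0.63 with an estimated correlation). Lists that did not pass were jasmonate (16 of 63 rose, 13 fell), ethylene (43 of 160 rose, 26 fell), auxin (34 of 159 rose, 40 fell), abscisic acid with dehydrins (19 of 64 rose, 16 fell), and cytokinin with gibberellin (38 of 121 rose, 34 fell). Their camera adjusted p were 0.19, 0.17, 0.71, 0.71 and 0.91. Adjusted over the list alone these were 16 and 13, 42 and 25, 34 and 40, 19 and 16, and 39 and 35. In the auxin list 52 members were described as 5NG4 (18 rose, 16 fell), and in the cytokinin list 57 as glucosyltransferases (9 rose, 21 fell). Lipoxygenase 1, TraesCS2B02G555400, an enzyme of oxylipin synthesis, rose from 0.169 ± 0.059 to 3.73 ± 0.4 FPKM, and the ethylene-responsive factor RAP2-13, TraesCS7D02G469200, from 0.705 ± 0.29 to 12.7 ± 0.58. WRKY and NAC factors had 66 rises and 112 falls among 301 (71 and 116 adjusted over the list alone; camera adjusted p = 0.038, adjusted p = 0.56 with an estimated correlation, 0.12 under a stricter filter, and 0.11 without KN9204 normal potassium replicate 1, 0.078 without low potassium replicate 1 and 0.11 without low potassium replicate 2). A NAC factor, TraesCS2D02G101400, rose from 0.0109 ± 0.019 to 1.65 ± 0.46 FPKM. MYB and bHLH factors (106 of 378 rose, 91 fell; 111 and 102 adjusted over the list alone), heat shock proteins (23 of 104 rose, 37 fell; 23 and 38), and glutathione S-transferases with other scavengers of reactive oxygen (33 of 118 rose, 27 fell; 34 and 32) did not pass (camera adjusted p = 0.2, 0.28 and 0.84). In the heat shock list 36 members were described as factors or STI (9 rose, 4 fell). The other 68 had 14 rises, 33 falls and a median log2 of -0.36, and were not tested as a list of their own. Transcription factor MYB86 fell in both named copies, TraesCS7A02G304500 from 2.8 ± 0.37 to 0.236 ± 0.093 FPKM and TraesCS7D02G300000 from 4.42 ± 0.47 to 0.365 ± 0.074.

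Among the largest changes in KN9204 outside these lists were a GDSL esterase/lipase, TraesCS1A02G144100, which rose from 0.0212 ± 0.018 to 14.9 ± 0.79 FPKM, and oxalate oxidase 2, TraesCS4B02G033100, a wall enzyme that releases hydrogen peroxide, which rose from 0.0888 ± 0.15 to 9.74 ± 2 (log2 6.57 ± 0.77, adjusted p = 4.9e-05). Receptor kinase ZmPK1, TraesCS6D02G400200, fell from 16.1 ± 3.5 to 0.0888 ± 0.1 FPKM (log2 -7.53 ± 0.62, adjusted p = 1.1e-05). Markers of other tissues were measured beside these groups. Of 21 photosynthesis genes 12 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.00011, and adjusted p = 0.023 with an estimated correlation). Their levels were low: a photosystem I subunit, TraesCS2A02G114400, went from 0 to 1.33 ± 0.76 FPKM, at least 7.72-fold higher. Of 10 seed storage genes 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.43).

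In all, 28437 of 62053 genes (45.8%) changed in KN9204, 13774 upward and 14663 downward, and 9505 of them changed at least 2-fold. Of the 27 lists 15 passed, and potassium transporters and photosynthesis were the only lists past the threshold with an estimated correlation. Median, mean and test differed in sign for scavengers of reactive oxygen, jasmonate, auxin, abscisic acid, cytokinin with gibberellin, and MYB with bHLH factors. When libraries were scaled by total counts only, 60.1% of called genes were higher in place of 48.4%, and quantile normalization gave 54.1%.

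The second comparison asked the same of the sensitive cultivar BN207. Potassium transporter 1 rose from 27.9 ± 2.6 to 84.3 ± 3.8 FPKM in its 4A copy (SD, n = 3; TraesCS4A02G410200, log2 1.53 ± 0.09 SE, edgeR adjusted p = 6.2e-09), from 28.6 ± 2.9 to 77.6 ± 3.6 in the 4B copy (TraesCS4B02G310300, log2 1.38 ± 0.09) and from 22.3 ± 2.4 to 56.6 ± 2.5 in the 4D copy (TraesCS4D02G308200, log2 1.28 ± 0.09). Aluminium-activated malate transporter genes annotated ALMT3, of a family of organic anion channels, also rose. TraesCS2A02G402400 went from 0.0489 ± 0.02 to 5.85 ± 0.6 FPKM (log2 6.73 ± 0.56) and TraesCS2B02G420600 from 0.0626 ± 0.088 to 6.21 ± 1 (log2 6.51 ± 0.66). TraesCS2D02G399700 went from 0.0171 ± 0.03 to 3.37 ± 0.53 (log2 7.46 ± 0.79). The starting levels were near 0, so the sizes of these log2 values are uncertain. These copies rose in KN9204 too (log2 4.82, 3.97 and 2.84), and the interaction had edgeR adjusted p of 0.19, 0.097 and 0.028. Histone and replication genes had a median log2 of -2.12 (-2.1 with bounds) and class III peroxidases of -2.12 (-2.04 with bounds).

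Of the 52 potassium transporters and channels, 28 rose and 8 fell in BN207 (28 and 8 adjusted over the list alone; median log2 0.43, camera adjusted p = 0.00014, adjusted p = 0.081 with an estimated correlation). The AKT1-like channel genes, chosen after their values were seen, rose from 10.4–15.1 to 25.4–29.5 FPKM (TraesCS3A02G233800, TraesCS3B02G265500 and TraesCS3D02G219600, log2 1.23, 0.7 and 1.41). CBL and CIPK genes had 33 rises and 20 falls among 74 (33 and 20 adjusted over the list alone; camera adjusted p = 0.058, and 0.045 with scaling by total counts only). CBL-interacting protein kinase 17, TraesCS1A02G080600, rose from 6.33 ± 0.6 to 23.4 ± 0.96 FPKM. Of the 28 exchangers, HKT carriers and pumps, 19 rose and 8 fell (19 and 8 adjusted over the list alone; camera adjusted p = 0.0095, adjusted p = 0.16 with an estimated correlation, and 0.24 without the expression filter). Cation/H(+) antiporter 19, TraesCS5B02G031800, rose from 0.661 ± 0.17 to 6.07 ± 0.69 FPKM. Other calcium signalling genes had 10 rises and 40 falls (10 and 40 adjusted over the list alone; camera adjusted p = 0.00048, adjusted p = 0.21 with an estimated correlation). A calmodulin-binding protein, TraesCS5B02G095800, went from 21.9 ± 1.1 to 1.97 ± 0.26 FPKM. Nitrate and ammonium genes (17 rose, 37 fell; 17 and 37 adjusted over the list alone), phosphate and sulfate transporters (28 rose, 30 fell; 28 and 30) and metal acquisition (36 rose, 33 fell; 37 and 33) did not pass (camera adjusted p = 0.069, 0.92 and 0.7). High-affinity nitrate transporter 2.1, TraesCS6B02G044000, fell from 0.56 ± 0.08 FPKM to 0, at least 6.18-fold lower, and an Nramp-domain gene, TraesCS4D02G036000, of a family of metal carriers, rose from 0.957 ± 0.11 to 6.75 ± 0.67.

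Peroxidases had 27 rises and 259 falls in BN207 (28 and 264 adjusted over the list alone; camera adjusted p = 1.9e-19, adjusted p = 0.064 with an estimated correlation). The 17 ascorbate and glutathione members had 0 rises and 8 falls, and the other 316 had 27 and 251. Peroxidase 1, TraesCS1D02G318200, went from 24.4 ± 2 FPKM to 0 in all 3 low libraries, at least 228-fold lower. Histone and replication genes had 20 rises and 263 falls (21 and 268 adjusted over the list alone; camera adjusted p = 8.7e-36, adjusted p = 0.12 with an estimated correlation). The 34 cyclin-dependent kinases supplied 10 of the rises and 9 of the falls. Histone H2A, TraesCS5B02G439500, fell from 3.04 ± 0.29 to 0.161 ± 0.098 FPKM. Ribosomal protein genes had 26 rises and 334 falls (27 and 337 adjusted over the list alone; median log2 -0.55, camera adjusted p = 2.9e-07, adjusted p = 0.48 with an estimated correlation). Wall loosening and remodelling had 30 rises and 112 falls (30 and 112 adjusted over the list alone; camera adjusted p = 7.9e-07, adjusted p = 0.12 with an estimated correlation). Phenylpropanoid and lignin synthesis had 12 and 66 (12 and 67 adjusted over the list alone; camera adjusted p = 2e-10, adjusted p = 0.12 with an estimated correlation). A putative cinnamyl alcohol dehydrogenase, TraesCS2D02G069800, which makes lignin precursors, fell from 0.78 ± 0.15 to 0.0112 ± 0.019 FPKM. Casparian strip and suberin genes had 2 rises and 12 falls (2 and 13 adjusted over the list alone; camera adjusted p = 0.024, adjusted p = 0.16 with an estimated correlation, and 0.11 without the expression filter). Pathogenesis-related genes had 45 rises and 126 falls (46 and 126 adjusted over the list alone; camera adjusted p = 0.00014, adjusted p = 0.13 with an estimated correlation). Pathogenesis-related protein 1, TraesCS7B02G068400, went from 2.76 ± 0.7 FPKM to 0, at least 14.1-fold lower.

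Abscisic acid, dehydrin and LEA genes had 7 rises and 37 falls in BN207 (7 and 37 adjusted over the list alone; median log2 -0.83, or -0.76 with bounds; camera adjusted p = 0.0015, adjusted p = 0.46 with an estimated correlation). Abscisic stress-ripening protein 1, TraesCS3A02G510100, went from 0.93 ± 0.35 FPKM to 0, at least 7.16-fold lower. Jasmonate genes had 18 rises and 31 falls (18 and 31 adjusted over the list alone; camera adjusted p = 0.032, adjusted p = 0.21 with an estimated correlation, 0.092 by limma on log2(FPKM + 1), and 0.053 without BN207 low potassium replicate 2). Putative lipoxygenase 3, TraesCS5D02G513100, fell from 24.8 ± 4.7 to 1.7 ± 1.4 FPKM. Heat shock proteins, chaperones of the stress response, had 43 rises and 17 falls (41 and 17 adjusted over the list alone; camera adjusted p = 0.014, adjusted p = 0.48 with an estimated correlation, and 0.12 under a stricter filter). A heat shock protein, TraesCS1B02G352400, rose from 0.418 ± 0.039 to 3.07 ± 0.76 FPKM. Members described as factors or STI made up 36 of that list, of which 11 rose and 0 fell. Of the lists that did not pass, ethylene had 48 rises and 49 falls, auxin 37 and 73, cytokinin with gibberellin 31 and 55, sugar transport 27 and 38, aquaporins 15 and 17, WRKY with NAC 94 and 96, MYB with bHLH 115 and 119, and scavengers of reactive oxygen 38 and 46. Their camera adjusted p were 0.76, 0.42, 0.3, 0.15, 0.95, 0.79, 0.56 and 0.49. Adjusted over the list alone these were 48 and 49, 37 and 73, 32 and 58, 27 and 39, 15 and 17, 94 and 96, 115 and 121, and 40 and 46. Sucrose:fructan 6-fructosyltransferase, an enzyme of fructan storage, fell from 24.2 ± 3.5 to 0.41 ± 0.14 FPKM (TraesCS4A02G485400) and from 35.6 ± 5.9 to 0.564 ± 0.13 (TraesCS7D02G009400). Aquaporin PIP2-5, TraesCS5B02G570800, fell from 4.03 ± 0.31 to 0.364 ± 0.15 FPKM, and aquaporin 7, TraesCS6D02G212900, rose from 2.26 ± 0.86 to 26.5 ± 7.5.

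The largest rises in BN207 by fitted log2 value included a (1,3;1,4) beta glucanase, TraesCS1A02G234600, from 0.9 ± 0.11 to 59.5 ± 9.6 FPKM. L-allo-threonine aldolase, TraesCS2A02G382700, went from 0.11 ± 0.071 to 9.92 ± 3.7. Senescence-associated proteins were also among them: TraesCS7B02G019600 from 0.011 ± 0.019 to 5.75 ± 1.5, and TraesCS7D02G531600 from 0 to 1.76 ± 0.91, at least 13.3-fold higher. The largest falls by fitted log2 value included falls to 0 in low potassium. Among them were a cortical cell-delineating protein, TraesCS1A02G210100 (7.14 ± 1.8 FPKM, at least 17.6-fold lower), and O-methyltransferase ZRP4, TraesCS1A02G335500 (2.92 ± 0.28, at least 30.7-fold). A benzoxazinoid glucoside beta-glucosidase, TraesCS2D02G594400 (1.67 ± 0.84, at least 26.2-fold), and disease resistance protein RPP13, TraesCS7A02G032200 (1.44 ± 0.038, at least 56-fold), were others. Fitted values of genes at 0 are no bounds, so other genes may have fallen further. RPP13 had stood in BN207 normal potassium at a small part of its level in KN9204, 12.4 ± 0.49 FPKM. Photosynthesis genes had 17 rises and 2 falls (17 and 2 adjusted over the list alone; camera adjusted p = 0.0082, adjusted p = 0.11 with an estimated correlation, and 0.074 without the expression filter). The photosystem I subunit TraesCS2A02G114400 stood at 2.64 ± 0.46 FPKM in low potassium. Of 10 seed storage genes 5 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.56). A globulin, TraesCS1A02G317500, rose from 1.38 ± 0.33 to 11.1 ± 0.99 FPKM and a glutenin subunit, TraesCS1D02G000200, from 0.559 ± 0.26 to 5.64 ± 0.93.

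In all, 38020 genes (61.3%) changed in BN207, 18183 upward and 19837 downward, and 16604 changed at least 2-fold. Which direction was in the majority depended on scaling: 47.8% of called genes were higher, against 52.2% with total counts only and 56.8% with quantile normalization. Of the 27 lists 14 passed and 0 passed with an estimated correlation, against 21 by limma's fry, which tests each list on its own. Median, mean and test differed in sign for metal acquisition, aquaporins, WRKY with NAC, and MYB with bHLH factors.

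**Figure D3:**
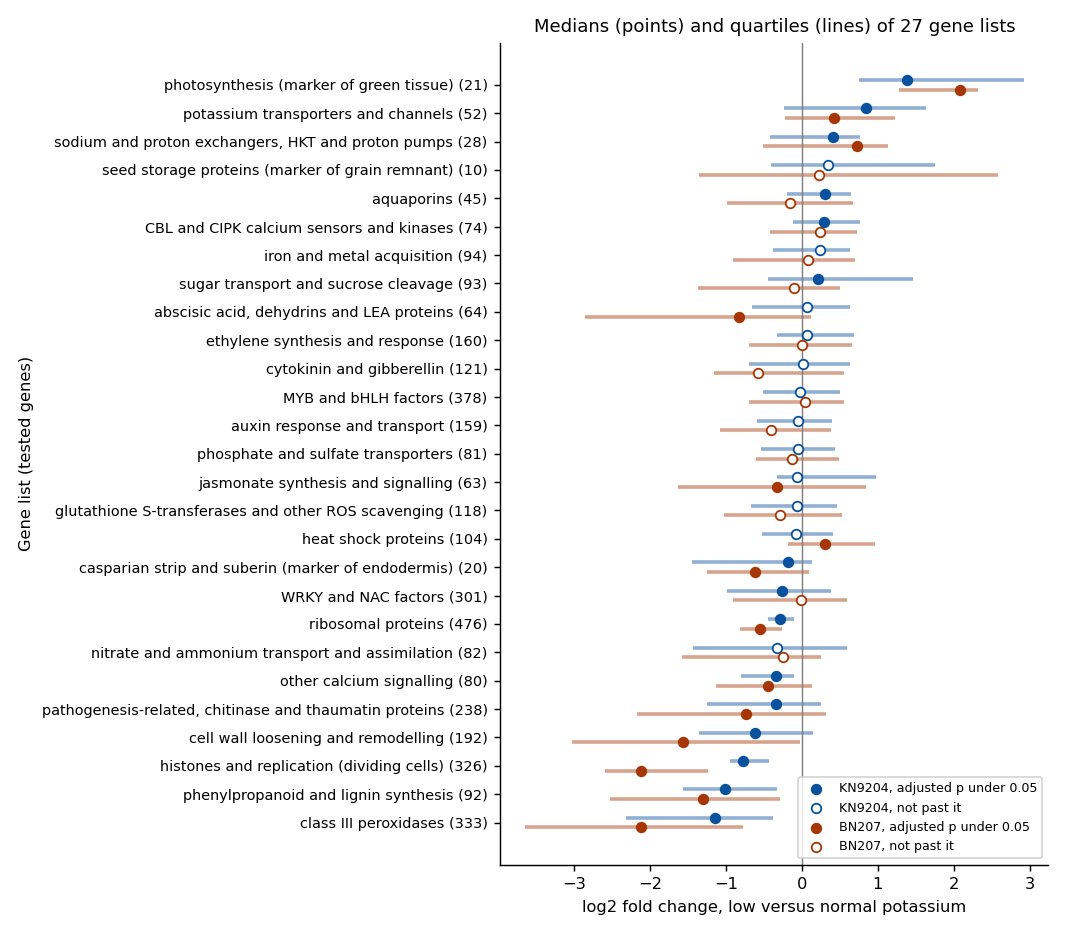
Median log2 fold change of 27 gene lists (points) with lower and upper quartiles of their genes (lines), low versus normal potassium, in KN9204 (blue) and BN207 (brown), with the number of tested genes in brackets. Filled points passed camera with the preset correlation. Histones and replication lie at -0.77 in KN9204 and -2.12 in BN207, and potassium transporters at 0.85 and 0.43.

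The third comparison, the interaction, asked whether the potassium response differed between the cultivars. Histone and replication genes fell less in KN9204 than in BN207: 220 of 326 had a higher response in KN9204, 13 a lower one and 93 were not called (234 and 14 adjusted over the list alone; median difference log2 1.3, camera adjusted p = 1.5e-29, adjusted p = 0.18 with an estimated correlation). Of that list the 34 cyclin-dependent kinases had 6 higher and 10 lower, and the other 292 genes had 214 higher and 3 lower with a median of 1.39. The log2 response of potassium transporters was higher in KN9204, by more rise or less fall, for 17 of 52 and lower for 3 (17 and 4 adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.18 with an estimated correlation). The difference was log2 1.65 ± 0.13 for the 4A copy of potassium transporter 1 (TraesCS4A02G410200, edgeR adjusted p = 1.2e-06), 0.44 ± 0.12 for the 4B copy (TraesCS4B02G310300, adjusted p = 0.018, and 0.055 with quantile normalization) and 0.74 ± 0.12 for the 4D copy (TraesCS4D02G308200). In low potassium the 4A copy stood at 74.8 ± 1.7 FPKM in KN9204 and 84.3 ± 3.8 in BN207 (SD, n = 3; log2 difference -0.1 ± 0.09, adjusted p = 0.38), and in normal potassium at 7.7 ± 0.83 and 27.9 ± 2.6.

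Potassium transporter 7, a further HAK family member chosen after its values were seen, rose in KN9204 in all 3 copies, from 6.97–8.62 to 18.5–21.7 FPKM. In BN207 it stood at 14.6 and 13.7 FPKM in the 2A copy (TraesCS2A02G116700, log2 -0.15 ± 0.07, adjusted p = 0.063) and at 16.9 and 16.8 in the 2D copy (TraesCS2D02G118400, log2 -0.07 ± 0.07, adjusted p = 0.43). It rose by log2 0.29 ± 0.07 in the 2B copy (TraesCS2B02G135900). The interaction was log2 1.25, 1.3 and 1.01 in that order, with adjusted p of 1.2e-06, 1.9e-06 and 1.4e-05. The AKT1-like channels differed by log2 0.51, 0.62 and 0.39 (TraesCS3A02G233800, TraesCS3B02G265500 and TraesCS3D02G219600, the last with adjusted p = 0.014, and 0.12 with quantile normalization), the CIPK14 copies by 2.46 ± 0.24 (TraesCS4B02G120400) and 2.16 ± 0.2 (TraesCS4D02G118500), HKT1;4-2 by 4.3 ± 0.33 (TraesCS2B02G451400) and HKT7-A1 by 4.51 ± 0.82 (TraesCS2D02G428200). The size of the HKT7-A1 difference is uncertain, since that gene stood at 0.0315 FPKM in KN9204 normal potassium. In low potassium the CIPK14 copies stood at 5.7 and 9.15 FPKM in KN9204 and at 5.15 and 8.56 in BN207 (edgeR adjusted p = 0.27 and 0.3). In normal potassium they stood at 0.604 and 0.815 FPKM in KN9204 and at 3.09 and 3.52 in BN207. CIPK17 (TraesCS1A02G080600) was not called for the interaction (log2 -0.29 ± 0.14, edgeR adjusted p = 0.14). The CBL and CIPK list did not pass for the interaction (median 0.08, camera adjusted p = 0.1). Of its 74 genes 20 were higher, 7 lower and 47 not called (24 higher and 8 lower adjusted over the list alone).

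Lists with more rise or less fall in KN9204 included jasmonate (28 genes higher and 4 lower of 63; 32 and 5 adjusted over the list alone; camera adjusted p = 1e-06, and adjusted p = 0.048 with an estimated correlation). Sugar transport and sucrose cleavage did the same (37 and 6 of 93; 39 and 6 adjusted over the list alone; camera adjusted p = 9.2e-08, and adjusted p = 0.021 with an estimated correlation). Lipoxygenase 3, TraesCS5D02G513100, differed by log2 3.23 ± 0.82 (adjusted p = 0.021, and 0.054 without BN207 low potassium replicate 2), SUC3, TraesCS2B02G533300, by 3.27 ± 0.49 and the 4A copy of sucrose:fructan 6-fructosyltransferase, TraesCS4A02G485400, by 2.72 ± 0.33. Abscisic acid and dehydrin genes had 27 higher and 3 lower of 64 (33 and 3 adjusted over the list alone; camera adjusted p = 9.2e-08, adjusted p = 0.24 with an estimated correlation). Wall loosening had 69 and 12 of 192 (81 and 13 adjusted over the list alone; camera adjusted p = 1.4e-05, adjusted p = 0.24 with an estimated correlation). Peroxidases had 114 and 34 of 333, of which ascorbate and glutathione members supplied 7 and 0 (133 and 35 adjusted over the list alone; camera adjusted p = 7.2e-05, adjusted p = 0.32 with an estimated correlation). Ribosomal proteins had 103 and 6 of 476 (97 and 6 adjusted over the list alone; camera adjusted p = 0.004, adjusted p = 0.71 with an estimated correlation). Nitrate and ammonium genes had 29 and 17 of 82 (31 and 23 adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.16 with an estimated correlation, and 0.11 by limma on log2(FPKM + 1)). Phenylpropanoid genes had 23 and 6 of 92 (23 and 6 adjusted over the list alone; camera adjusted p = 0.019, adjusted p = 0.56 with an estimated correlation, 0.43 by limma on log2(FPKM + 1), and 0.053 without KN9204 low potassium replicate 3). Aquaporins had 14 and 4 of 45 (18 and 5 adjusted over the list alone; camera adjusted p = 0.027, adjusted p = 0.62 with an estimated correlation, 0.076 without KN9204 normal potassium replicate 2, 0.091 without KN9204 low potassium replicate 1, 0.074 without BN207 normal potassium replicate 2 and 0.066 without BN207 low potassium replicate 2). Heat shock proteins went the other way, with 3 higher and 36 lower of 104 (4 and 40 adjusted over the list alone; camera adjusted p = 7.7e-07, adjusted p = 0.25 with an estimated correlation). WRKY and NAC factors had 31 and 65 of 301 (32 and 69 adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.56 with an estimated correlation).

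**Figure D4:**
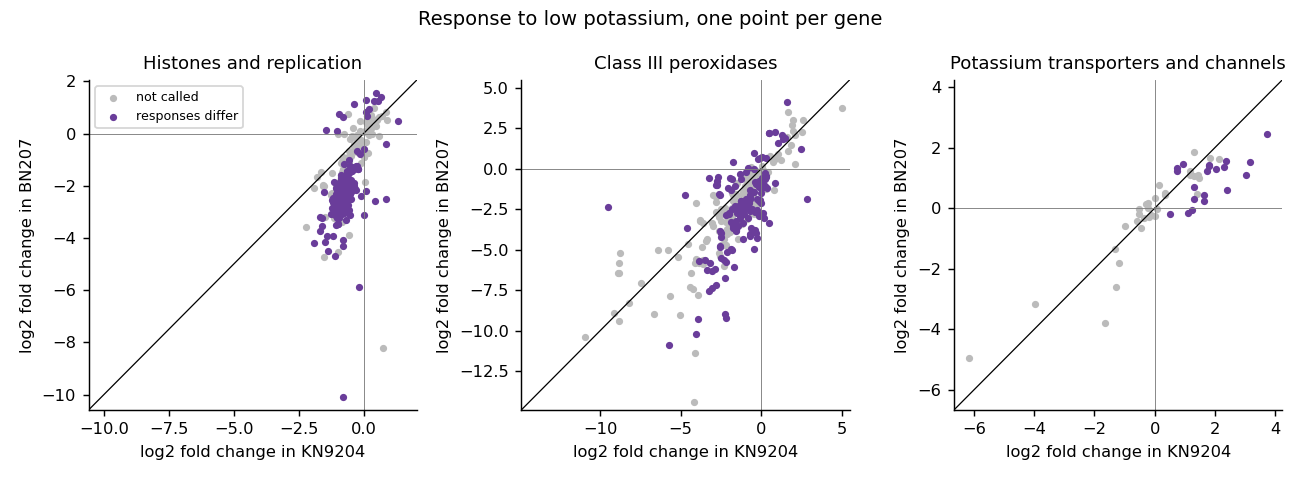
Fitted log2 fold change in low versus normal potassium in KN9204 (x axes) and BN207 (y axes) for each gene of 3 lists, with purple points for genes whose responses differed and a black line where both are equal. Fitted values of genes at 0 in a whole group are no bounds. Most histone and replication genes lie below the line, with medians of -0.77 and -2.12.

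In all, 16324 genes (26.3%) differed in response, 9357 higher and 6967 lower in KN9204, and 76.6% of them changed more in BN207. The higher share of 57.3% became 47.1% with quantile normalization. The responses correlated across genes, which are not independent replicates, at Pearson r of 0.588 and Spearman rho of 0.677. The cultivars shared no control libraries. Both cultivars called 22342 genes, 94.6% in the same direction, with 10072 higher in both against 4036 for independent lists and 11061 lower in both against 4687. The median and mean of the sodium exchanger list differed in sign, and its test did not pass (8 genes higher and 6 lower of 28; 8 and 6 adjusted over the list alone; camera adjusted p = 0.7).

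The fourth comparison set KN9204 against BN207 under normal potassium. The largest differences by fitted log2 value were of genes detected in 1 cultivar. Disease resistance protein RPM1 in the 7B copy, TraesCS7B02G453400, an immune receptor, stood at 44 ± 0.85 FPKM in KN9204 and at 0 in BN207 (SD, n = 3), at least 1000-fold higher. A further RPM1 gene, TraesCSU02G082800, stood at 8.68 ± 0.42 and 0, at least 218-fold higher. Cysteine-rich receptor kinase 16, TraesCS2B02G027000, stood at 26.9 ± 2.7 and 0, at least 706-fold higher. Argininosuccinate lyase, TraesCS5B02G299700, an enzyme of arginine synthesis, stood at 0 in KN9204 and 14.5 ± 1.5 FPKM in BN207, at least 186-fold lower. A mannose/glucose-specific lectin, TraesCS5A02G433600, stood at 0 and 9.13 ± 0.67, at least 160-fold lower. A benzoxazinoid dioxygenase, TraesCS2A02G051700, stood at 0 and 10.5 ± 1.5, at least 119-fold lower. Each of these genes was at 0 in every library of that cultivar under low potassium as well. Whether such a gene is silent, absent or unlike the reference in sequence was not tested, and the bounds do not cover this.

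WRKY and NAC factors were higher in KN9204 in 141 of 301 cases and lower in 16 (150 and 19 adjusted over the list alone; camera adjusted p = 2.4e-06, adjusted p = 0.41 with an estimated correlation). Pathogenesis-related genes were higher in 96 and lower in 18 of 238 (98 and 20 adjusted over the list alone; camera adjusted p = 2.6e-05, adjusted p = 0.41 with an estimated correlation). Potassium transporters were higher in 4 and lower in 17 of 52 (5 and 18 adjusted over the list alone; camera adjusted p = 0.037, adjusted p = 0.41 with an estimated correlation, 0.061 in a fit of these 6 libraries alone, and 0.069 without KN9204 normal potassium replicate 3). Ribosomal proteins were higher in 18 and lower in 233 of 476 (20 and 257 adjusted over the list alone; camera adjusted p = 8e-05, adjusted p = 0.71 with an estimated correlation). Histone and replication genes were higher in 35 and lower in 125 of 326 (37 and 139 adjusted over the list alone; camera adjusted p = 0.019, adjusted p = 0.78 with an estimated correlation, and 0.089 without KN9204 normal potassium replicate 1). Also higher in KN9204 were lignin synthesis, peroxidases, other calcium signalling and heat shock proteins, with camera adjusted p of 0.0043, 0.0066, 0.0098 and 0.037. For these 4 lists adjusted p = 0.64, 0.64, 0.64 and 0.71 with an estimated correlation. Without KN9204 normal potassium replicate 1, other calcium signalling had adjusted p = 0.051 and heat shock proteins 0.057. Heat shock proteins also had 0.051 without BN207 normal potassium replicate 1 and 0.073 with quantile normalization. In all, 24495 genes (39.5%) differed, 12857 higher and 11638 lower in KN9204, and the higher share of 52.5% became 38% with scaling by total counts only and 48.5% with quantile normalization. The median, mean and test differed in sign for nitrate and ammonium genes, sugar transport and seed storage proteins.

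Under low potassium the cultivars differed in 31972 genes (51.5%), 18036 higher and 13936 lower in KN9204. The higher share of 56.4% became 49.6% with total counts only, 46.9% with quantile normalization and 48.2% by limma on log2(FPKM + 1). RPP13, TraesCS7A02G032200, stood at 7.07 ± 0.61 FPKM in KN9204 and 0 in BN207 (SD, n = 3), at least 275-fold higher. The GDSL esterase/lipase TraesCS1A02G144100 stood at 14.9 ± 0.79 and 0, at least 146-fold higher. Ubiquitin carboxyl-terminal hydrolase 2, TraesCS1A02G432600, stood at 0 and 4.48 ± 0.028, at least 117-fold lower. Wall-associated receptor kinase 4, TraesCS6B02G002700, stood at 0 and 7.55 ± 1.3, at least 105-fold lower. The esterase/lipase in BN207 and this receptor kinase in KN9204 were at 0 under normal potassium too. Absence of the gene or a sequence unlike the reference was not tested there either. The difference in histone and replication genes had the opposite sign to that under normal potassium, with 214 higher and 33 lower in KN9204 (220 and 34 adjusted over the list alone; camera adjusted p = 1.3e-07, adjusted p = 0.52 with an estimated correlation). Peroxidases were higher in 215 and lower in 27 of 333 (222 and 28 adjusted over the list alone; camera adjusted p = 4.1e-07, adjusted p = 0.28 with an estimated correlation). Sugar transport genes were higher in 55 and lower in 11 of 93 (56 and 11 adjusted over the list alone; camera adjusted p = 8.6e-05, adjusted p = 0.092 with an estimated correlation). Potassium transporters, with 11 higher and 7 lower of 52 (8 and 5 adjusted over the list alone), did not pass (camera adjusted p = 0.97). In all 12 lists passed, every one higher in KN9204, and 0 passed with an estimated correlation. The others were pathogenesis-related proteins, wall loosening, lignin synthesis, abscisic acid, jasmonate, other calcium signalling, aquaporins, WRKY with NAC factors and scavengers of reactive oxygen. For these 9 lists adjusted p = 0.15, 0.28, 0.34, 0.43, 0.15, 0.35, 0.55, 0.56 and 0.35 with an estimated correlation. Without KN9204 low potassium replicate 3, WRKY with NAC factors had adjusted p = 0.069 and scavengers 0.067. WRKY with NAC factors had 0.064 without BN207 low potassium replicate 3, and scavengers 0.077 under a stricter filter. The median, mean and test differed in sign for potassium transporters, CBL with CIPK, metal acquisition and seed storage proteins.

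By the chromosome in the gene ID, 51.4% of 2603 tested genes of 1B differed between the cultivars under normal potassium and 60.4% under low potassium, against 44.5% and 54.3% on 6B and 33.5% to 41.5% and 47.1% to 52.2% on the other chromosomes. The 1B difference lay at the low end of its ID numbers. Among 705 tested genes numbered below 1500 (the number in the ID divided by 100), 581 were lower and 30 higher in KN9204 under normal potassium, with a median log2 of -1.56, while the other 1898 genes of 1B had a median of -0.05. These ranges were chosen after the values were seen. Genes of this part that stood high in BN207 included a metallothionein, TraesCS1B02G042200, at 31.3 FPKM in KN9204 and 260.4 in BN207, and peroxidase N, TraesCS1B02G115800, at 16.6 and 79.4, both under normal potassium and chosen after their values were seen.

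**Figure D5:**
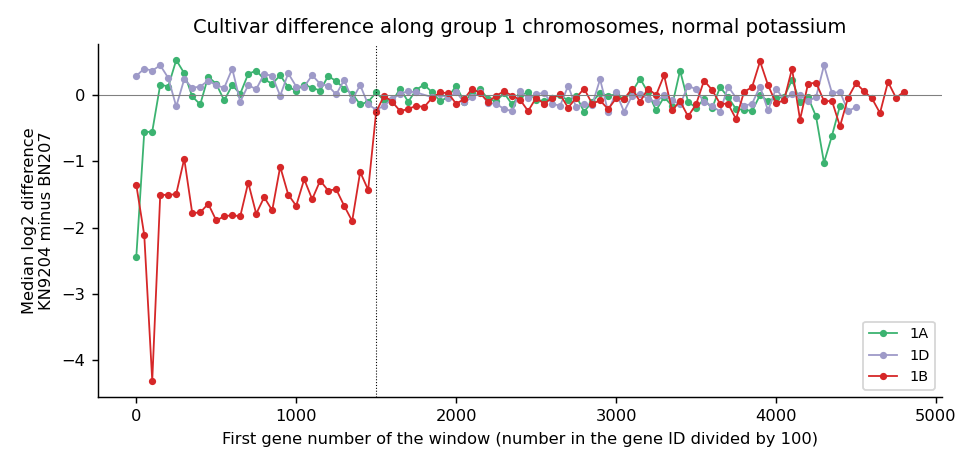
Median log2 difference between KN9204 and BN207 under normal potassium (y axis) in windows of 50 gene numbers with at least 10 tested genes, in order of the number in the gene ID (x axis), for chromosomes 1A, 1B and 1D. The dotted line marks number 1500. On 1B the last window before it lies at -1.43 and the windows after it at -0.25 and -0.01.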

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

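The tests of mixed RNA, another haplotype, switching by potassium, the share of dividing cells, residuals and lists between cultivars were chosen after the results they measure were seen, and the other tests of splits were set before. The bounds of the scaling test were set before its values were seen, though scaling by total counts only was added after seeing the data. The interaction of cultivar and potassium was called for 16324 genes by edgeR. Of 100 splits of the 12 libraries into 4 groups of 3, 2 gave as many genes (highest other 18570), 11 as many as its 13 lists (highest other 17) and 38 as many as its 385 GO and KEGG terms (highest other 719). These splits mix cultivars and potassium levels within groups, so they do not decide whether chance can be excluded for an interaction. In the split with 18570 genes 1 of the 6 libraries on the added side came from low potassium, so that it mostly separated normal from low potassium. With the separate effects of cultivar and potassium kept and their residuals split 100 times, limma gave 18201 genes for the real split (highest other 1, 1 split as large). It gave 409 terms (highest other 422, median of the others 162, 2 splits as large). Both counts by limma passed a share of 0.05, which argues against chance for the gene count. The residuals hold any interaction, however, which widens the spread in the other splits and can lower their gene counts. For terms the evidence is weaker, because another split gave more and the counts were not adjusted for one another. Single terms are not covered. Chance was not excluded for the 11 lists by limma (highest other 14, 5 splits as large). If the libraries of a group came from the same culture, these splits do not cover differences between cultures. The remaining comparisons allow 10 splits each, too few for a share under 0.05. The real split gave 28437 genes in KN9204 (highest other 3), 38020 in BN207 (highest other 2), 24495 between cultivars under normal potassium (highest other 1) and 31972 under low potassium (highest other 1), each reached by 1 split. For lists it gave 15 in KN9204 and 14 in BN207 (highest other 12 in both, 1 split as large). Between cultivars it gave 9 lists under normal potassium (highest other 9, 4 splits as large) and 12 under low potassium (highest other 15, 4 splits as large). For terms it gave 469 in KN9204 (highest other 486, 3 splits as large) and 679 in BN207 (highest other 480, 1 split as large).

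Lists whose response differed between the cultivars by camera with the preset correlation had median log2 differences of 1.3 for histones and replication, 0.88 for abscisic acid and dehydrins, 0.79 for wall loosening, and 0.76 for peroxidases. Smaller ones were 0.62 for jasmonate, 0.51 for lignin synthesis, 0.43 for aquaporins, 0.36 for sugar transport, 0.26 for ribosomal proteins, 0.23 for potassium transporters, 0.22 for nitrate and ammonium genes, -0.11 for WRKY with NAC factors and -0.36 for heat shock proteins. With an estimated correlation only jasmonate (adjusted p = 0.048) and sugar transport (0.021) still passed. In the order above the others had adjusted p of 0.18, 0.24, 0.24, 0.32, 0.56, 0.62, 0.71, 0.18, 0.16, 0.56 and 0.25.

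Among transport genes the interaction log2 difference was 1.65 for TraesCS4A02G410200, 0.44 for TraesCS4B02G310300 and 0.74 for TraesCS4D02G308200 (potassium transporter 1). Potassium transporter 7 differed by 1.25 for TraesCS2A02G116700, 1.01 for TraesCS2B02G135900 and 1.3 for TraesCS2D02G118400. AKT1-like channels differed by 0.51 for TraesCS3A02G233800, 0.62 for TraesCS3B02G265500 and 0.39 for TraesCS3D02G219600. The difference was 4.3 for HKT1;4-2 (TraesCS2B02G451400), 4.51 for HKT7-A1 (TraesCS2D02G428200) and 3.27 for SUC3 (TraesCS2B02G533300). It was 2.13 for aquaporin PIP2-5 (TraesCS5B02G570800), -2.59 for aquaporin 7 (TraesCS6D02G212900), -1.23 for cation/H(+) antiporter 19 (TraesCS5B02G031800) and -0.74 for the Nramp-domain gene TraesCS4D02G036000. For the putative Na+/K+ transporter TraesCS7A02G418500 it was 1.29, with adjusted p = 0.017, and 0.058 without BN207 normal potassium replicate 2. For ALMT3 TraesCS2D02G399700 it was -4.61, with adjusted p = 0.028, and 0.093 and 0.17 without KN9204 normal potassium replicates 1 and 2. HKT7-A1 in KN9204 and this ALMT3 gene in BN207 stood near 0 under normal potassium (0.0315 and 0.0171 FPKM), so the sizes of their differences are uncertain. The HKT8 gene TraesCS4B02G370800 differed with adjusted p = 0.02, and 1 without BN207 low potassium replicate 3.

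In other genes it was 2.46 and 2.16 for the CIPK14 copies TraesCS4B02G120400 and TraesCS4D02G118500, 2.25 for the calmodulin-binding protein TraesCS5B02G095800, -6.77 for ZmPK1 (TraesCS6D02G400200) and 5.07 for oxalate oxidase 2 (TraesCS4B02G033100). It reached 2.72 and 1.79 for sucrose:fructan 6-fructosyltransferase (TraesCS4A02G485400 and TraesCS7D02G009400) and -3.01 for the beta glucanase TraesCS1A02G234600. It stood at 2.29 for histone H2A (TraesCS5B02G439500), -2.17 for a heat shock protein (TraesCS1B02G352400), -8.25 for the senescence-associated protein TraesCS7B02G019600, -0.51 for peroxidase N (TraesCS1B02G115800) and 0.53 for the clock gene PRR1 (TraesCS6D02G207100), the last chosen after its values were seen. The sizes for oxalate oxidase 2, ZmPK1 and TraesCS7B02G019600 are fitted values and uncertain, because a group stood near 0. These levels were 0.0888 FPKM in KN9204 normal potassium, 0.0888 in KN9204 low potassium and 0.011 in BN207 normal potassium. Peroxidase N lies in the low-numbered range of 1B, whose 705 genes had a median response of log2 -0.4 in KN9204 and 0.07 in BN207. For lipoxygenase 1 (TraesCS2B02G555400) the interaction difference was 1.56, with adjusted p = 0.0033, and 0.51 by limma on log2(FPKM + 1). For lipoxygenase 3 (TraesCS5D02G513100) it was 3.23, with adjusted p = 0.021, and 0.054 without BN207 low potassium replicate 2.

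Genes at 0 in a whole group differed with adjusted p = 1.2e-05 for CBL4 (TraesCS1B02G370600), 0.0077 for a senescence-associated protein (TraesCS7D02G531600), 0.00027 for a cortical cell-delineating protein (TraesCS1A02G210100) and 0.019 for ZRP4 (TraesCS1A02G335500). Adjusted p was 4.4e-10 for RPP13 (TraesCS7A02G032200), 0.001 for a benzoxazinoid beta-glucosidase (TraesCS2D02G594400), 8e-06 for abscisic stress-ripening protein 1 (TraesCS3A02G510100) and 0.00013 for pathogenesis-related protein 1 (TraesCS7B02G068400). It was 0.00015 for a xyloglucan endotransglucosylase (TraesCS4A02G172600), 7.4e-07 for ubiquitin hydrolase 2 (TraesCS1A02G432600), 7.6e-07 for ribosomal protein L9 (TraesCS3B02G011900) and 1e-05 for histone H4.3 (TraesCS3B02G378900).

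A set of 79 genes had FPKM of at least 1 in BN207 under normal potassium and at most 0.05 under low potassium, against 9 the other way, and 14 and 8 in KN9204. Mixing of KN9204 RNA into the BN207 normal libraries was argued against, because 69.9% of 113 genes at FPKM 5 or more in both KN9204 groups and off in BN207 low potassium stood under 0.005 of the KN9204 level in BN207 normal potassium. A potassium response of the set as a whole in BN207 alone was argued against too. The 52 with a mean FPKM of at least 1 over the KN9204 libraries had a median log2 change there of -2.47 (quartiles -4.14 and -1.24), with 43 falls. A fall in KN9204 was not always a switching off. RPP13 (TraesCS7A02G032200) went there from 12.4 to 7.07 FPKM and histone H4.3 (TraesCS3B02G378900) from 17.2 to 10.5. Both were at 0 in BN207 low potassium. Switching off in BN207 alone stays open for such genes and for the 2 that rose and the 7 not called in KN9204. It also stays open for the genes of the set outside the 52. Plants with another haplotype among the BN207 normal seedlings may contribute, since 17 of the 113 genes stood at 0.02 to 0.3 of the KN9204 level in each of the 3 libraries (median ratio 0.118), but this cannot be told apart from a potassium response of single genes without sequence variants. RPP13, ribosomal protein L9 (TraesCS3B02G011900) and histone H4.3, named above for their interaction, were among these 17.

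Scaling between libraries cannot be told apart as a part of the larger fall of histone and replication genes in BN207, since the lowest median difference over 3 other scalings was 0.99, just under the bound of 1 set for arguing against it. The median difference of all genes under these scalings lay between -0.041 and 0.086, so the list stood apart from the other genes. Median-of-ratios scaling and quantile normalization hold that median near 0 by construction. It therefore does not decide whether scaling is the whole of the difference. A lower share of dividing cells in the BN207 low potassium roots as sampled is a candidate explanation. The response was higher in KN9204 for 45 and lower for 3 of 103 kinesins, for 5 and 0 of 6 ribonucleotide reductase genes and for 8 and 0 of 17 DNA polymerase genes, the rest not called, with a lowest median difference of 0.51. The 5 genes of proliferating cell nuclear antigen went against this, with 2 rises and 0 falls in BN207. Whether cultivar or potassium supply sets such a share was not tested.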

How the results depend on the processing

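The DESeq2, counts divided by 4, total counts only and term alternatives, and all those for lists between cultivars, were chosen after seeing the data, and limma on log2(FPKM + 1), the planned test, became an alternative then. Of 206 called results of single genes, 189 kept their side of the threshold under every alternative that tested the gene and 194 without each replicate, and 0 reversed. The stricter filter left 185 of the 206 to test, and all 185 kept their side. These genes were mostly chosen for large changes in the same data, so the share does not describe all calls. With quantile normalization 14105 of 16324 interaction calls were kept. Of 63 called list results 45 kept their side of the threshold under every alternative but the estimated correlation, and 0 reversed. With at least 2-fold change the counts were 9505 in KN9204, 16604 in BN207, 7329 for the interaction, and 9780 and 13473 between cultivars under normal and low potassium. With an estimated correlation 2, 0 and 2 lists passed in KN9204, BN207 and the interaction, 0 and 0 between cultivars, and 0, 0 and 0 terms, while fry called 23 lists for the interaction and 20 and 21 between cultivars under normal and low potassium. The cause was not tested. The correlation of responses, 0.588, was 0.66 with a pseudocount of 0.1, 0.325 without a filter, 0.632 with a stricter one, 0.67 with quantile normalization, 0.677 with library weights, 0.681 by limma, 0.621 with counts divided by 4, 0.557 by DESeq2, and 0.561 to 0.584 without each library. The highest chromosome share, 51.4% on 1B, became 1.2% on 6B for genes detected in 1 cultivar alone, fewer by construction, with 0.69% on 1B. Why the order changed was not tested. Total counts only moved the median of all genes by 0.101 in KN9204 and to -0.148 between cultivars under normal potassium, and the higher shares from 48.4% to 60.1% and from 52.5% to 38%. Quantile normalization moved the higher share of the interaction from 57.3% to 47.1%. Same-numbered replicates did not pair, with correlations of -0.116 to 0.0518, and not every sample correlated best with its own number. With the replicate number as a block the counts were 27196, 36960, 14926, 23237 and 30933. At 75924470 to 88552154 counts per library, depth limits genes near the floor of 12 counts.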

Other observations

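Genes, gene groups and tests in this part were chosen after their values were seen. Autophagy genes, whose products recycle cell contents, rose in 19 of 41 cases in KN9204 and 32 in BN207, with 0 falls in either. The 5 leucine breakdown genes rose in both cultivars, with median log2 of 2.43 and 3.49, and all 5 rose further in BN207. Fasciclin-like proteins of the cell wall fell in 25 of 36 cases in KN9204 and 32 in BN207, with 0 rises. Benzoxazinoid genes, which make cereal defence compounds, had 3 rises and 6 falls among 23 in KN9204 and 0 and 18 in BN207, and the response was higher in KN9204 for 14 and lower for 2. SWEET sugar transporters had 6 rises and 1 fall among 11 in KN9204 and 4 and 6 in BN207, and the response was higher in KN9204 for 8 and lower for 0. Of 791 disease resistance genes 178 rose and 187 fell in KN9204, and 288 rose and 144 fell in BN207. Their log2 response was lower in KN9204 for 158 and higher for 41.

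Clock genes were counted by potassium supply as well. Of 9 pseudo-response regulators 9 rose in KN9204 and 7 in BN207, and 3 of 3 ELF3 genes rose in both. PRR95 (TraesCS5D02G326200) went from 5.67 ± 0.19 to 19.9 ± 0.83 FPKM in KN9204 and from 8.9 ± 0.94 to 29 ± 1.5 in BN207 (SD, n = 3), and PRR73 (TraesCS4D02G199600) from 22.8 ± 1.8 to 40.9 ± 1.9 and from 29.8 ± 0.97 to 50.8 ± 1.8. ELF3-B1 (TraesCS1B02G477400) rose by log2 0.76 and 1.08 and 1 of 3 LHY genes (TraesCS7A02G553800) by 1.29 and 1.43, while the other LHY genes were not called in either cultivar. The gigantea gene rose by log2 0.27 in KN9204 and was not called in BN207 (log2 -0.07). The hours at which the groups were harvested are not given in the sources used here.

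The low-numbered end of chromosome 1B stood lower in KN9204, with a median log2 of -1.56 under normal and -1.92 under low potassium over 705 genes. A difference in depth or scaling was argued against, because the rest of 1B had a median of -0.05. Regulation of genes one by one was argued against as well, because the longest run of consecutive windows of 50 ID numbers with a median under -0.5 along all of 1B held 30 windows, against at most 4 in 1000 shuffles of the genes of 1B and at most 3 on the 20 other chromosomes. A short arm of 1B in KN9204 that differs from the reference, so that part of its reads was placed on the A and D copies, is a candidate explanation. Under normal potassium the same range on 1A and 1D stood 0.12 and 0.19 above the rest of its chromosome, against at most 0.02 on 18 other chromosomes. Under low potassium it stood 0.1 and 0.13 above, against at most 0.05. The lowest-numbered windows of 1A went the other way, with medians of -2.45, -0.56 and -0.55 under normal potassium. The median potassium response of the 1B range was log2 -0.4 in KN9204 and 0.07 in BN207. Over the rest of 1B it was 0.02 and -0.04. Whether the candidate accounts for these values was not tested. The size of such a segment in bases was not measured, since no coordinates were used here.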
